A study of Mus musculus with 18 samples.

How the data were processed

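The study measured single-cell RNA in early mouse adrenogonadal development, in embryos that carry an Nr5a1 transgene and a GFP reporter transcript. Per the labels, tissues were dissociated with enzymes, viable cells were sorted for every sample except the E12.5 ovaries and testes, and each 10x Chromium run took 3000 to 7000 cells, with the 3′ kit of version 2. There were 18 libraries in 9 groups of 2 replicates. These were XX and XY posterior trunks at E9.0, XX and XY urogenital ridges at E10.5 and at E11.5, and XX ovaries, XY testes and XY adrenal glands at E12.5. The series design calls the 2 replicates of each group independent; which litters or how many embryos made up a replicate is not stated, so the p-values measure the spread between these samples only. Stage, the part of the body taken, the date and, at E12.5, the lack of sorting change together, so a difference between stages cannot be told apart from these.

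Per the submitters' processing notes, reads were processed with Cell Ranger 2.1 on GRCm38.p5 (mm10). The deposited matrix holds raw UMI counts, with no normalization by the authors, for 18193 gene symbols and 72273 cells; how genes and cells were filtered is not stated, and the fewest cells with a gene was 20. The matrix holds 1642.26 M UMIs, with a median of 20556 UMIs and 4555 genes per cell and a minimum of 2823 UMIs. Cells were assigned to libraries from the prefix of their names. The separate lists of kept cells matched that assignment for 17 of 18 libraries; the list for adrenal gland replicate 1 was identical to that of the XY posterior trunk E9.0 replicate 1, and the name prefix was used. Chromosomes and positions come from GENCODE vM21 on GRCm38, in which 17740 of the symbols were found.

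Depth per library was as follows, each as cells, total UMIs in M and median UMIs per cell. XX posterior trunk E9.0 had 2337, 81.9 and 33387 in replicate 1 and 2930, 104 and 33424.5 in replicate 2, and XY posterior trunk E9.0 had 3719, 124 and 31492, and 4074, 132 and 30556.5. XX urogenital ridge E10.5 had 2558, 70.5 and 25684.5, and 4566, 111 and 22664.5, and XY urogenital ridge E10.5 had 2752, 67.2 and 22611.5, and 5086, 125 and 22855. XX urogenital ridge E11.5 had 3991, 87.6 and 18942, and 2281, 45.0 and 16476, and XY urogenital ridge E11.5 had 5124, 95.7 and 16364.5, and 5274, 111 and 17644.5. Ovaries had 5138, 87.4 and 14260.5, and 4545, 85.1 and 16590. Testes had 3025, 54.7 and 15640, and 7577, 155 and 17344, and adrenal glands had 3569, 42.9 and 10074, and 3727, 62.6 and 13392.

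Cells were scaled to 10000 counts, log-transformed, reduced to 2500 variable genes found in at least 50 cells (scaled values clipped at 10) and 40 principal components, and grouped by Leiden clustering of a graph of 15 neighbours at resolution 1.0 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, seed 1). This gave 45 clusters, of which 35 were named from marker lists: a name needed at least 3 of its markers among the 60 genes with the highest ratio to the other cells, more markers unique to its list than any other list had there, and no other list with more markers among the first 10. The other 10 clusters, with 22.3% of cells, stayed unnamed. Doublet scores came from simulated pairs within each library; at 0.8% per 1000 cells, 2567 cells (3.55%) were marked, and they were left out only as an alternative.

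Nr5a1-positive cells are cells with at least 1 Nr5a1 UMI, leaving out clusters named erythroid, megakaryocyte, immune, endothelial, germ, neural, neural crest or hepatic. The 4 posterior trunk libraries had 7 to 14 such cells, under the minimum of 20, so no test of Nr5a1-positive cells was made at E9.0. Shares of cells with an Nr5a1 UMI were taken after drawing 8000 UMIs per cell, the 5th percentile of depth in steps of 500, and compared with exact two-sided permutation tests. With 2 libraries against 2 the smallest such p is 0.333, so these tests cannot reach 0.05.

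For each comparison, counts were summed per library and tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3, TMM scaling, filterByExpr) with Benjamini-Hochberg adjustment at 0.05. One fit of 14 libraries (15824 genes, common dispersion 0.0423, 7 residual degrees of freedom) covered Nr5a1-positive cells, and one of 18 libraries (17858 genes, 0.0471, 9) covered whole libraries; effective library sizes of the first were 10.2 to 49.8 M counts. The comparisons were XY against XX at each stage, adrenal gland against testis, E11.5 against E10.5, E12.5 gonads against E11.5, and the change of the sex difference from E11.5 to E12.5. In 6 cell classes of the 4 gonad libraries, testis was compared with ovary within the class. Among Wt1-positive cells at E10.5 and at E11.5, Nr5a1-positive cells were compared with Nr5a1-negative cells in 8 sums with the library as a block. Standard errors are the log2 fold change over the square root of F. Genes of the gate (Nr5a1, GFP and, in the last comparison, Wt1) are not reported.

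Genes named in a comparison are the 10 with the largest positive and the 10 with the largest negative log2 fold change among those with an adjusted p under 0.05, a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups (for the change of the sex difference, between the per-date differences; for paired cells, the same direction in each library), and then members of the lists below. Symbols of predicted genes and clones are counted but not named. A gene with no count in one group is given as "at least" a fold, from 3 counts per library as the floor, which covers counting error only. The lists were fixed with the comparisons, the rule and the alternatives before the data were examined. They were steroidogenesis; cholesterol synthesis and uptake; testis supporting; ovary supporting; coelomic epithelium and gonad specification; epithelial; mesenchyme and extracellular matrix; S phase; G2 and M phase; cyclin-dependent kinase inhibitors; Hox clusters; WNT targets and components; Hedgehog components; Notch components; retinoic acid handling; BMP, activin and TGF-beta components; FGF and RTK components; imprinted; germ cell markers; female germ cell and meiosis; male germ cell; Y-linked; X inactivation and escape; dissociation stress; hypoxia and glycolysis; mitochondrially encoded; haemoglobin and erythroid; endothelial markers; immune markers; neural crest and chromaffin markers; and nephric markers. These 31 lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, each adjusted over the lists of a comparison.

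The pipeline was tested on simulated data with 100 genes planted at 2-fold and 100 at 4-fold. In Nr5a1-positive cells, 43% to 49% of the 2-fold and 95% to 99% of the 4-fold sex differences were found, against 14% and 87% for the change of the sex difference and 7% and 61% in gonadal interstitial progenitors. Between 2 and 23 unchanged genes were called per comparison and none with the wrong sign. Lists were simulated for the sex comparison at E12.5 alone, where 0 of 31 were called with nothing planted. The simulated genes were drawn independently and without effects of date, and changes were planted only in genes above a floor of expression. These rates therefore need not hold for all tested genes of the real data, and the list result not for lists of correlated genes.

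Per the dates in the labels, the XX and XY libraries of a stage with the same replicate number share a date. To check the pairing, the replicate 2 minus replicate 1 differences were correlated across genes (genes are not independent replicates) between XX and XY. In Nr5a1-positive cells the correlation was 0.297 at E10.5, 0.703 at E11.5 and 0.650 at E12.5, and in whole libraries it was 0.635 at E9.0, 0.363 at E10.5, 0.718 at E11.5 and 0.348 at E12.5. The planned test has no block, and a fit with the date as a block was run beside it. Other alternatives were DESeq2 1.42.0 size factors in the same test, the DESeq2 Wald test, no filter on low counts, at least 2 Nr5a1 UMIs, no cluster left out, all cells of the clusters named coelomic epithelium and gonadal progenitor, pre-granulosa, Sertoli, fetal Leydig or adrenocortical in place of the Nr5a1 gate, doublets left out, a fit of the compared groups only, and each compared library left out in turn. For paired cells they were no block and negative cells matched on UMIs. For shares they were no thinning, 16000 UMIs, at least 2 UMIs, and resolutions of 0.5 and 2.0. An alternative without cells that carry transcripts of the other sex was added after the data were seen. Figures were drawn with matplotlib 3.10.9. Results on some genes are not reported here.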

Results

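The 18 libraries held 2281 to 7577 cells and 42.9 M to 155 M UMIs each. There were 2 libraries in each of 9 groups: XX and XY posterior trunks at E9.0, XX and XY urogenital ridges at E10.5 and at E11.5, and ovaries, testes and XY adrenal glands at E12.5. The comparisons ask how the tissues that give rise to gonad and adrenal cortex differ between the sexes, between stages and between the glands. Expression is in CPM after TMM scaling, given as mean ± SD over the libraries of a group. Fold changes are log2 ± SE. Positions are on GRCm38 and identifiers are the deposited gene symbols. Unless a gene is given as a member of a list, all libraries of its higher group lay above all libraries of its lower group.

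Nr5a1 encodes the nuclear receptor that marks the shared precursors of gonad and adrenal cortex. At 8000 UMIs per cell the share of cells with an Nr5a1 UMI was 0.0769 ± 0.0122% in XX and 0.0929 ± 0.0967% in XY posterior trunks at E9.0 (SD, n = 2 libraries per group). At E10.5 it was 9.15 ± 4.31% in XX and 13.9 ± 1.96% in XY ridges, and at E11.5 18.4 ± 2.25% and 24.5 ± 3.52%. At E12.5 it was 29.9 ± 2.02% in ovaries, 35.8 ± 9.93% in testes and 17.6 ± 7.80% in adrenal glands. Germ cells, which should lack Nr5a1, had a UMI in 6.46 ± 1.96% of cells in ovaries and 12.4 ± 6.68% in testes, and these shares read as background. Their median depths before thinning were 25566 and 24850 UMIs in ovaries, against 14260.5 and 16590 for all cells. In testes they were 31284 and 30017, against 15640 and 17344. The exact two-sided permutation p of XY against XX was 1 at E9.0, 0.333 at E10.5 and at E11.5, and 0.667 at E12.5. With 2 against 2 libraries 0.333 is the smallest possible.

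**Figure D1:**
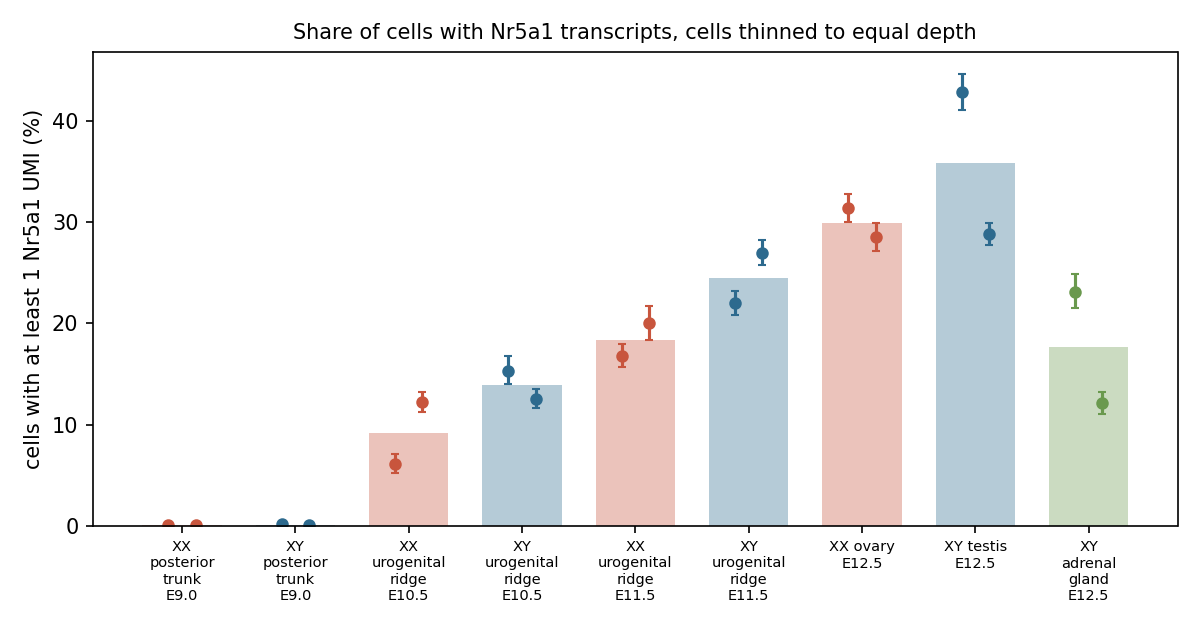
Share of cells with an Nr5a1 UMI at 8000 UMIs per cell (y axis, percent) in each group (x axis), with a point per library and the group mean. The 4 posterior trunk libraries lie near 0 and the gonads reach means of 29.9% and 35.8%.

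Cell classes named from markers followed the tissues. Sertoli cells, the supporting cells of the testis, made up 17.3 ± 0.276% of testis cells. Pre-granulosa cells, the supporting cells of the ovary, were 39.2 ± 5.77% of ovary cells (SD, n = 2). Germ cells were 27.0 ± 5.68% of ovary cells. Adrenal glands held 13.4 ± 4.02% adrenocortical cells and 39.5 ± 5.13% neural crest, Schwann precursor and chromaffin cells. Posterior trunks were mostly somite, with 66.5 ± 1.07% in XX and 57.5 ± 5.67% in XY. Of 45 exact two-sided permutation tests, of class shares and of the Nr5a1 shares above, 25 reached p = 0.333, the smallest possible value. The testes differed from each other: gonadal interstitial progenitors were 0.992% of cells in replicate 1 (95% Clopper-Pearson interval 0.670 to 1.41) and 31.8% in replicate 2 (30.7 to 32.8), intervals that cover the counting of cells alone. An unnamed cluster led by Cyp17a1, Ren1 and Cbln1 held 1360 of 3025 cells in replicate 1 and 156 of 7577 in replicate 2.

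At E10.5, the only genes called between Nr5a1-positive cells of XX and XY ridges were of the sex chromosomes. In simulated data this comparison found 44% of the 2-fold changes, so autosomal differences of that size are not excluded. Xist, the RNA that silences an X chromosome, was at 1292 ± 3.26 CPM in XX and 0.616 ± 0.00957 CPM in XY (log2 fold change −11.02 ± 1.34, adjusted p = 0.031, edgeR, n = 2 per group). Kdm5d, a Y-linked histone demethylase, was at least 77.6-fold higher in XY (15.7 ± 0.465 CPM against 0, adjusted p = 0.031). These were the only genes of 15824 to pass, with 462 at an unadjusted p under 0.05. The fit with dates as blocks called 0 (Xist and Kdm5d adjusted p = 0.930), the DESeq2 Wald test 9 and a fit of these 4 libraries alone 5. Without XX ridge replicate 1 the count was 0 (adjusted p = 0.171 for Xist and 0.201 for Kdm5d), without XX replicate 2 it was 0 (0.0814 and 0.178). Without XY replicate 1 it was 0 (0.702 and 0.137). Without XY replicate 2 it was 6, with Xist at 0.0905 and Kdm5d at 0.0447.

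Of the 4 tested genes of the Y-linked list at E10.5, 1 was higher in XY and 3 did not pass (4 higher adjusted over the list alone). Of 11 genes of X inactivation and escape 1 was lower and 10 did not pass (5 adjusted over the list alone). Both lists were called by camera, with adjusted p = 0.0026 for each with an estimated correlation. Of the 26 testis supporting and 26 ovary supporting genes, 0 passed in edgeR. The preset correlation called 16 more lists without a single called member, among them Hox clusters lower (adjusted p = 1.2e-05, and adjusted p = 0.53 with an estimated correlation), germ cell markers higher (0.00014, and adjusted p = 0.42 with an estimated correlation) and dissociation stress higher (0.00023, and adjusted p = 0.53 with an estimated correlation). None of these 16 was called with an estimated correlation.

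At E11.5, genes of Sertoli cell differentiation were higher in XY Nr5a1-positive cells. Sox9, the transcription factor that directs Sertoli cell fate (chromosome 11, 112782224 to 112787760), was at 261 ± 69.5 CPM in XY and 68.9 ± 2.42 CPM in XX (log2 1.92 ± 0.27, adjusted p = 0.011, n = 2 per group). Fgf9, a growth factor that maintains Sox9, rose from 3.80 ± 0.156 CPM in XX to 24.9 ± 11.02 CPM in XY (2.71 ± 0.30, adjusted p = 0.0031). Mt3, a metallothionein, rose from 0.596 ± 0.0261 to 26.3 ± 1.48 CPM (5.46 ± 0.44, adjusted p = 0.00074). Ptgds, a prostaglandin D synthase, was higher by 4.09 ± 0.70, Mmd2 by 4.06 ± 0.62, Gatm, an enzyme of creatine synthesis, by 2.32 ± 0.29 and Gas7 by 2.14 ± 0.20 (adjusted p = 0.0014 to 0.024). Lower in XY was Fst, the activin-binding follistatin, at 7.52 ± 1.54 CPM against 39.1 ± 22.4 in XX (−2.39 ± 0.37, adjusted p = 0.016). Lower too were Siglecg (−1.58 ± 0.20), Ccdc61 (−1.09 ± 0.20), Frmd6 (−1.04 ± 0.18) and Gtf2a1, a general transcription factor (−0.91 ± 0.17, adjusted p = 0.0057 to 0.045 for these 4). From the sex chromosomes, Uty (5.73 ± 0.93) and Kdm5d (at least 105-fold) were higher, and Xist (−6.10 ± 1.04) and Kdm6a, an X-linked histone demethylase that escapes X inactivation (−0.74 ± 0.14), lower. Xist was at 1.11 and 33.4 CPM in the XY libraries, and Uty at 0.0340 and 1.06 CPM in the XX libraries. XY replicate 2 held 100 cells, and XX replicate 2 held 47, with transcripts of the other sex and none of their own.

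In total 83 genes passed at E11.5, 73 higher and 10 lower in XY, of which 69 were autosomal, with 879 at an unadjusted p under 0.05. Of 26 testis supporting genes 6 rose and 20 did not pass (16 adjusted over the list alone): Sox9, Fgf9, Aard, Mmd2, Ptgds and Sox10. Camera called the list also with an estimated correlation (adjusted p = 0.0087). Of 26 ovary supporting genes 2 rose, among them Lgr5, a receptor of WNT signalling, Fst fell and 23 did not pass (2 higher and 4 lower adjusted over the list alone). Camera called it lower (adjusted p = 0.00062, and adjusted p = 0.12 with an estimated correlation). Of 24 FGF and RTK components Fgf9 and Etv5, a transcription factor downstream of FGF, rose (4 adjusted over the list alone, adjusted p = 0.0074, and adjusted p = 0.068 with an estimated correlation). The lists of Y-linked genes (2 higher of 4, adjusted p = 0.018) and X inactivation and escape (2 lower of 11, adjusted p = 0.0071) held with an estimated correlation. S phase was called at 0.040 with 0 members passing (adjusted p = 0.90 with an estimated correlation). Steroidogenesis, Hox, cell cycle and stress genes had 0 members pass of 23, 28, 26 and 23.

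Leaving out an E11.5 library leaves 1 library in an arm, and the other groups of the fit then supply the spread. Calls can be lost from the smaller number of libraries alone. Mt3 and Gas7 passed whichever library was left out. Without XX ridge replicate 1, 3 genes passed, and the values were 3.34 for Ptgds, 3.68 for Mmd2, 2.75 for Fgf9, 2.35 for Gatm, 1.96 for Sox9, 4.53 for Uty, −1.63 for Fst, −1.29 for Siglecg, −0.72 for Ccdc61, −0.91 for Frmd6, −0.68 for Gtf2a1 and −0.66 for Kdm6a, none passing. Xist was at adjusted p = 0.189 and Kdm5d at 0.107. Without XX replicate 2, 21 passed, not among them Ptgds (adjusted p = 0.0675), Mmd2 (4.44), Gatm (2.30), Sox9 (1.89), Xist (−6.35), Frmd6 (−1.16), Gtf2a1 (−1.10) and Kdm6a (−0.81). Without XY replicate 1, 15 passed, not among them Uty (5.82), Ptgds (4.27), Mmd2 (4.09), Sox9 (1.63), Fst (−2.61), Siglecg (−1.57), Ccdc61 (−1.22), Frmd6 (−1.02), Gtf2a1 (−0.72) and Kdm6a (−0.69). Without XY replicate 2, 19 passed, not among them Uty (5.64), Ptgds (3.88), Mmd2 (4.02), Fst (−2.19), Siglecg (−1.59), Ccdc61 (−0.98), Frmd6 (−1.06), Gtf2a1 (−1.12) and Kdm6a (−0.78). The DESeq2 Wald test called 149 genes, at least 2 Nr5a1 UMIs gave 174, a fit of these 4 libraries alone 35 and all cells of the named clusters in place of the gate 1, where Frmd6 turned to 0.029 and none of the genes named here passed (Sox9 0.33, Fgf9 0.45, Mmd2 1.48, Fst −0.97). At E11.5 these clusters were nearly all coelomic (12.45% and 12.8% of XX and XY cells) with at most 0.329% of any other named class, and the unnamed cluster with 48.7% and 45.8% of positive cells was not among them. In the fit of 4 libraries Uty, Ptgds, Fgf9, Xist, Fst, Siglecg, Ccdc61, Frmd6, Gtf2a1 and Kdm6a did not pass, nor did Gtf2a1 and Kdm6a without doublets. With dates as blocks Uty, Mmd2, Frmd6, Gtf2a1, Xist (adjusted p = 0.0984) and Kdm5d (0.0779) did not pass.

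At E12.5 the Nr5a1-positive cells of testis and ovary had separated into different programs. Amh, the hormone of Müllerian duct regression (chromosome 10, 80805243 to 80807648), was at 255 ± 123 CPM in testis and 5.50 ± 7.17 CPM in ovary (log2 5.58 ± 1.01, adjusted p = 0.0026, n = 2 per group). Ptgds reached 382 ± 111 against 10.9 ± 10.6 CPM (5.14 ± 0.66), and Dhh, the Hedgehog ligand of Sertoli cells, 95.1 ± 23.7 against 3.44 ± 4.54 (4.84 ± 0.97). Cbln1 was at 90.8 ± 6.58 against 3.14 ± 1.03 (4.86 ± 0.51) and Col9a3, a collagen chain, 163 ± 35.5 against 5.23 ± 6.18 (adjusted p = 0.0001 to 0.0047 for these 4). Bricd5 (5.28 ± 0.55) and Mmd2 (4.82 ± 0.60) followed, with the Y-linked Ddx3y (6.09 ± 1.17), Eif2s3y (5.46 ± 1.13) and Uty (5.27 ± 0.88). Except for Cbln1 these transcripts came mostly from replicate 1 in ovaries, with Amh at 10.6 and Dhh at 6.65 CPM against 0.430 and 0.232 in replicate 2. Without that library the values were 9.17 for Amh, 8.63 for Dhh, 6.75 for Ptgds, 7.53 for Col9a3, 6.40 for Bricd5, 6.99 for Mmd2, 14.20 for Ddx3y, 14.01 for Eif2s3y and 9.35 for Uty, and 5.21 for Cbln1. Without cells that carry transcripts of the other sex Amh was at 6.80 and Dhh at 6.28.

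In the ovary the transcription factor Irx3 (chromosome 8, 91798525 to 91802067) was at 321 ± 74.8 CPM against 1.49 ± 1.15 in the testis (−7.85 ± 0.48, adjusted p = 7.2e-06, n = 2 per group). Fst (chromosome 13, 114452290 to 114458951) was at 171 ± 7.27 against 1.51 ± 0.141 (−6.83 ± 0.45, adjusted p = 1.4e-05). Gng13, a G protein subunit, was at 249 ± 80.0 against 4.53 ± 0.359 CPM (−5.78 ± 0.35) and Foxl2, the transcription factor that keeps granulosa cell identity, at 24.4 ± 0.480 against 0.560 ± 0.0484 (−5.45 ± 0.55). Stum (−6.02 ± 0.48), the WNT target Sp5 (−4.45 ± 0.50), Lzts1 (−4.18 ± 0.45), the homeobox gene Msx1 (−4.06 ± 0.48) and Cntnap5a (−4.01 ± 0.37) were also lower in testis, as was Xist (−11.39 ± 1.33; adjusted p = 7.2e-06 to 0.0003 for these 8).

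**Figure D2:**
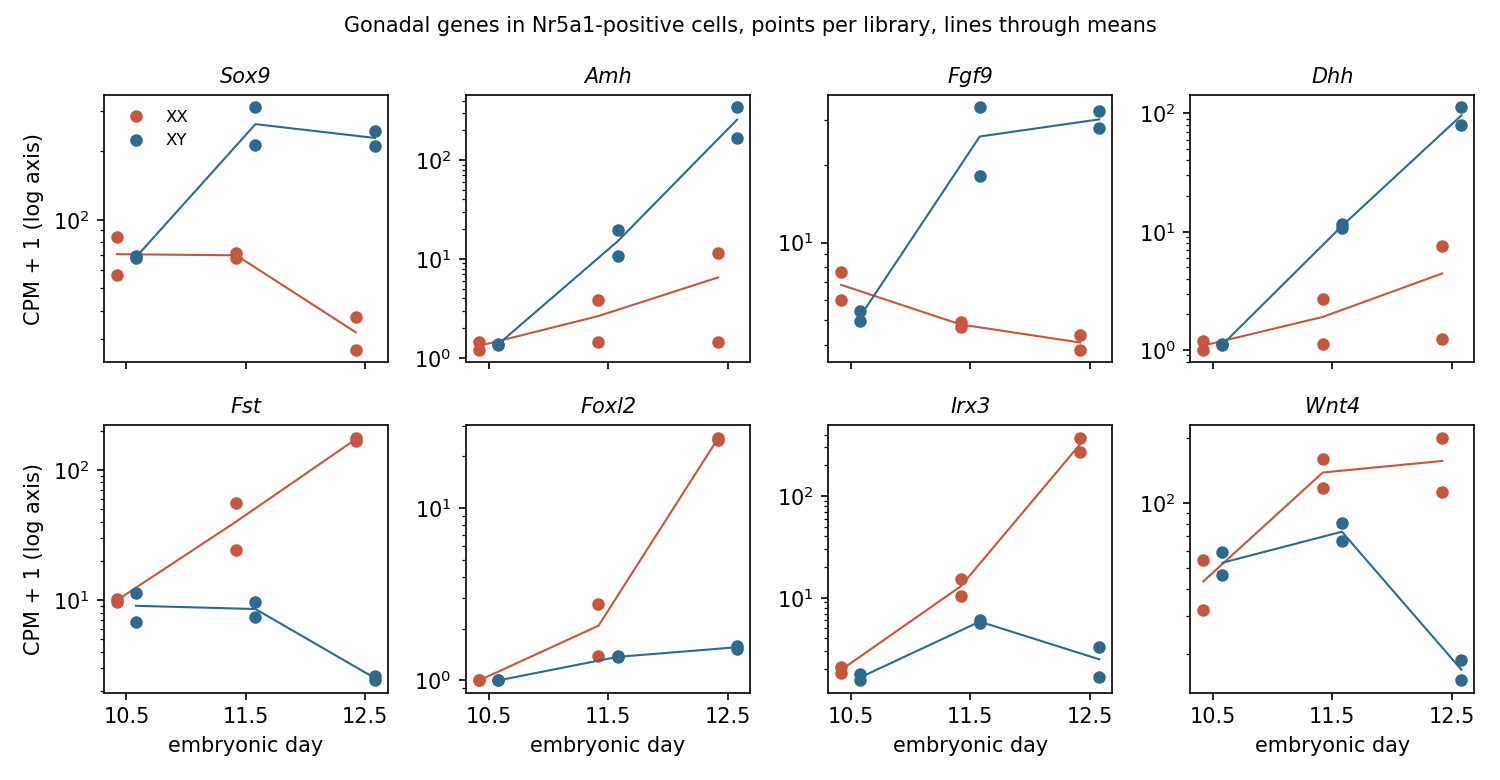
CPM on a log axis of gonadal genes in Nr5a1-positive cells of XX and XY libraries by embryonic day, with points per library and lines through the means. At E12.5 Irx3 has means of 321 CPM in ovaries and 1.49 CPM in testes, and Amh of 5.50 and 255 CPM.

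Of 26 testis supporting genes 24 rose in testis and 2 did not pass (25 adjusted over the list alone), with Fgf9 at 3.25 and Sox9 at 2.87. Of 26 ovary supporting genes 19 fell and 7 did not pass (1 higher and 22 lower adjusted over the list alone), with the WNT ligand Wnt4 at −3.28, Runx1 at −2.76, Bmp2 at −2.69 and Rspo1, an activator of WNT signalling, at −2.62. Both lists were called with an estimated correlation (adjusted p = 0.014 and 0.0023). All 26 G2 and M phase genes rose in testis (26 adjusted over the list alone), among them the mitotic kinases Plk1 (1.24) and Cdk1 (1.21) (adjusted p = 2.1e-20, and adjusted p = 0.16 with an estimated correlation). S phase rose in 10 of 26 (11 adjusted over the list alone; 0.0012, and adjusted p = 0.43 with an estimated correlation). Of 7 cyclin-dependent kinase inhibitors Cdkn1a (−2.47) and Cdkn1c (−2.18) fell (adjusted p = 0.098). Steroidogenesis rose in 12 and fell in 3 of 23 genes (12 and 3 adjusted over the list alone), with Cyp17a1 (4.34) and Cyp11a1, the side-chain cleavage enzyme (3.29) (adjusted p = 0.00023, and adjusted p = 0.24 with an estimated correlation). In all cells of the named clusters, which leave out the unnamed cluster led by Cyp17a1 (20.7% of pooled testis positive cells), Cyp17a1 was at −0.86 and Cyp11a1 at −0.55. That cluster held 1360 cells in testis replicate 1 and 156 in replicate 2, before the gate. Of 27 mesenchyme and matrix genes 14 rose (17 adjusted over the list alone), such as Fbn1 (1.22), Sparc (1.27) and Cdh11 (1.56) (adjusted p = 5.4e-08, and adjusted p = 0.24 with an estimated correlation). The positive cells were 72.1% pre-granulosa in ovaries, and 35.8% Sertoli, 23.2% interstitial progenitor and 24.2% unnamed in testes. These shares pool the replicates, and before the gate testis replicates 1 and 2 held 30 and 2408 interstitial progenitors.

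Among signalling lists, 12 of 25 WNT genes fell and 2 rose in testis (12 and 3 adjusted over the list alone), with Lef1 at −1.79 and Axin2, a feedback target, at −1.66 (adjusted p = 5.8e-05, and adjusted p = 0.19 with an estimated correlation). Of 13 Hedgehog components 5 rose and 2 fell (6 and 2 adjusted over the list alone), with the targets Gli1 (3.67) and Ptch1 (2.08) (0.020, and adjusted p = 0.42 with an estimated correlation). Of 15 Notch components 7 rose (7 adjusted over the list alone), with the targets Hes5 (3.76) and Heyl (1.83) (0.0026, and adjusted p = 0.25 with an estimated correlation). Among 24 FGF and RTK components 12 rose and 2 fell (12 and 3 adjusted over the list alone), with Etv5 at 2.72 (0.0017, and adjusted p = 0.066 with an estimated correlation). Retinoic acid handling (2 of 16 rose, adjusted p = 0.67) included Cyp26b1, the retinoic acid-degrading enzyme of the fetal testis, at 4.41. BMP, activin and TGF-beta components (6 rose and 5 fell of 25, 0.84), imprinted genes (4 and 6 of 22, 0.65) and Hox clusters (2 and 2 of 28, 0.45) were not called. Nor were coelomic epithelium and gonad specification (4 and 6 of 30, with the homeobox gene Emx2 at −1.87, 0.18), cholesterol synthesis (1 and 1 of 23, 0.94) and epithelial genes (0 and 2 of 19, 0.22).

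Markers of other cells moved as well. Of 11 female germ cell and meiosis genes 4 fell in testis (4 adjusted over the list alone), with Rec8, a meiotic cohesin, at −4.69 and Stra8, the inducer of meiosis, at −4.37 (adjusted p = 0.00081, and adjusted p = 0.22 with an estimated correlation), although the cluster named germ was outside the gate. Germ cell markers (0 rose and 3 fell of 13, 0.098) and male germ cell genes (3 and 1 of 14, 0.57) were not called. Nephric markers fell in 4 of 10 (7 adjusted over the list alone; 0.019, and adjusted p = 0.43 with an estimated correlation). All 4 tested genes of the Y-linked list rose (0.00039, and adjusted p = 0.24 with an estimated correlation). Of the genes of X inactivation and escape 4 of 11 fell (0.016, and adjusted p = 0.19 with an estimated correlation). Neural crest markers (2 rose of 12, 0.18), endothelial markers (1 rose of 12, 0.17), hypoxia and glycolysis (4 fell of 19, 0.18) were not called. Haemoglobin, immune, dissociation stress and mitochondrially encoded genes (0 of 11, 11, 23 and 13; 0.19, 0.91, 0.79 and 0.84) had no member pass. Haemoglobin took 6.44% of UMIs in ovary replicate 1 and 1.13% in replicate 2, and 2.09% and 3.16% in the testes. Ovary replicate 1 held 67 cells with Y-linked UMIs and no Xist, among them 18 of its 28 cells in the Sertoli class.

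At E12.5, 2932 genes passed, 1522 higher and 1410 lower in testis, with 4737 at an unadjusted p under 0.05 and 2742 of them autosomal. Without ovary replicate 1 the count was 1896 and without testis replicate 1 it was 1842, and with dates as blocks it was 4991. In a fit of the 4 gonad libraries alone Amh (5.56) and Dhh (4.83) did not pass, nor did Eif2s3y (5.36) in the DESeq2 Wald test.

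The change of the sex difference from E11.5 to E12.5 was largest for ovary genes. The XY minus XX difference fell by 6.54 ± 0.57 on the log2 scale for Irx3 and by 5.13 ± 0.44 for Gng13 (adjusted p = 0.00049 for both, 2 libraries in each of 4 groups). It fell by 4.78 ± 0.59 for Stum, by 4.45 ± 0.54 for Fst and by 4.22 ± 0.64 for Sp5 (adjusted p = 0.0028 to 0.0061). It also fell by 3.66 ± 0.58 for Lzts1 and by 3.53 ± 0.48 for Cntnap5a, and it rose by 4.25 ± 0.65 for Cbln1 and by 3.45 ± 0.47 for Defb19, a defensin of fetal Sertoli cells (adjusted p = 0.0034 to 0.0077). Each of these genes passed whichever library was left out. Of 26 ovary supporting genes 13 fell and 13 did not pass (18 adjusted over the list alone), with Irx5 at −4.36 and the protease Adamts19 at −3.24. The list held with an estimated correlation (adjusted p = 0.0011). The G2 and M phase list rose in 13 of 26 (26 adjusted over the list alone; adjusted p = 4.8e-26, and adjusted p = 0.18 with an estimated correlation). Testis supporting genes rose in 5 of 26, with Ptch1 at 2.06 (10 adjusted over the list alone; 2.3e-11, and adjusted p = 0.19 with an estimated correlation). WNT genes fell in 7 of 25 (2 higher and 10 lower adjusted over the list alone; 1.6e-05, and adjusted p = 0.19 with an estimated correlation).

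In all 590 genes passed the test of change, 259 up and 331 down, with 2458 at an unadjusted p under 0.05. The count was 206 without XX ridge E11.5 replicate 1, 178 without its replicate 2, and 356 and 370 without ovary replicates 1 and 2. It was 287 and 137 without XY ridge E11.5 replicates 1 and 2, and 225 and 221 without testis replicates 1 and 2. It was 1358 with dates as blocks, 344 with no cluster left out and 1139 in all cells of the named clusters.

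From E10.5 to E11.5, Nr5a1-positive cells, averaged over XX and XY, gained both ovary and testis supporting genes, and their named classes changed. At E10.5 the positive cells were 38.0% coelomic epithelium and gonadal progenitor in XX and 48.2% in XY, 25.7% and 19.9% mesonephric and other mesenchyme, and 27.8% and 26.2% unnamed. At E11.5 they were 16.3% and 17.6% coelomic, 15.3% and 16.2% interstitial progenitor, and 60.9% and 58.0% unnamed, with 48.7% and 45.8% in a single unnamed cluster. That cluster was led by Pnliprp2, Cpa1 and Nppc. At resolution 0.5 a cluster led by the same genes was named coelomic epithelium and gonadal progenitor (5408 cells, 98.3% from E11.5). The lower coelomic share at E11.5 may therefore depend on the resolution. A pair of unnamed clusters, with 17.1% and 8.12% of the XX positive cells at E10.5, had 0.0713 and 0.0457 Nr5a1 UMIs per 10000, against 0.0549 to 0.109 in the 3 main germ clusters. Kctd14 (chromosome 7, 97451323 to 97459557) rose from 28.3 ± 34.6 to 1048 ± 229.7 CPM (5.57 ± 0.64, adjusted p = 5.6e-05, n = 4 per stage). Lgals7, a galectin, rose from 9.92 ± 6.20 to 524 ± 73.0 CPM (5.79 ± 0.34, adjusted p = 8e-07). Aqp5, a water channel, rose at least 134-fold (21.6 ± 4.62 CPM against 0), the transglutaminase Tgm3 by 10.76 ± 0.37, the pluripotency factor Utf1 by 6.30 ± 0.39, and Gpr37 by 6.07 ± 0.40. The natriuretic peptide gene Nppc rose by 5.51 ± 0.48, Aldh3b1 by 5.51 ± 0.34, Vav3 by 5.50 ± 0.29 and the protease Adamts16 by 4.91 ± 0.36 (adjusted p = 2.3e-07 to 0.00011). Genes that fell included the arginase Arg1 (−5.44 ± 0.48, from 24.7 ± 14.6 to 0.552 ± 0.271 CPM), the somite homeobox gene Meox1 (−3.89 ± 0.42), the synuclein Sncg (−3.11 ± 0.22), and Bend4 (−2.88 ± 0.36). So did the retinol dehydrogenase Adh1 (−2.66 ± 0.39), the retinoic acid-binding Crabp2 (−2.61 ± 0.18, from 225 ± 55.0 to 36.5 ± 3.12 CPM), the mesenchymal T-box gene Tbx18 (−2.55 ± 0.26), the peptide hormone gene Cck (−2.45 ± 0.26), Hoxb2 (−2.41 ± 0.41) and the neurofilament gene Nefm (−2.37 ± 0.34; adjusted p = 1.9e-06 to 0.00075 for these 10).

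Of 26 ovary supporting genes 19 rose and 1 fell (20 and 1 adjusted over the list alone), with Sp5 at 4.49, Runx1 at 3.68, Bmp2 at 3.66 and Irx3 at 3.30. The list held with an estimated correlation (adjusted p = 0.012). Of 26 testis supporting genes 19 rose (20 adjusted over the list alone), with Ptgds at 5.36 (adjusted p = 7.9e-10, and adjusted p = 0.18 with an estimated correlation). In all cells of the named clusters Ptgds (4.04) did not pass, nor did Aldh3b1 (0.53) and Nefm (−0.55). Of 26 G2 and M phase genes 25 fell (25 adjusted over the list alone), with Plk1 at −1.28 and the kinase Aurka at −1.11 (1.7e-13, and adjusted p = 0.18 with an estimated correlation). In S phase 19 of 26 fell (20 adjusted over the list alone) (1.2e-07, and adjusted p = 0.23 with an estimated correlation). Of 28 Hox genes 22 fell and 1 rose (22 and 1 adjusted over the list alone), with Hoxb5 at −2.37 (2.1e-11, and adjusted p = 0.18 with an estimated correlation). Germ cell markers rose in 11 of 13 (11 adjusted over the list alone), with Dppa3 at 3.58 and Dazl at 3.16 (4.1e-06, and adjusted p = 0.18 with an estimated correlation), although the germ cluster was outside the gate. Dissociation stress genes rose in 19 and fell in 1 of 23 (19 and 1 adjusted over the list alone), with the immediate early genes Klf4 (3.39) and Egr1 (2.29) (4.2e-09, and adjusted p = 0.18 with an estimated correlation). Of 22 imprinted genes 10 fell and 2 rose, with Dlk1 at −2.17 (0.0041, and adjusted p = 0.23 with an estimated correlation). In all, 6179 genes passed, 3513 up and 2666 down, and 3354 in the named clusters. Stage and date change together here.

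From E11.5 to the E12.5 gonads, 1466 genes rose and 1717 fell. Id1, a target of BMP signalling, rose from 89.3 ± 10.2 to 345 ± 103 CPM (1.92 ± 0.17, adjusted p = 8e-05, n = 4 per stage). Gatm rose from 20.5 ± 15.9 to 82.8 ± 35.7 CPM (2.34 ± 0.20, adjusted p = 6.3e-05). Cyp17a1, the enzyme at the branch to androgens, rose by 4.42 ± 0.55, Kazald1 by 3.87 ± 0.18, Wfdc1 by 3.30 ± 0.28, Acsbg1 by 2.26 ± 0.17, Hs3st3a1 by 2.04 ± 0.22 and Rhox8, an X-linked homeobox gene of the gonad, by 1.85 ± 0.17 (adjusted p = 1.4e-06 to 0.00097). The lipase-related Pnliprp2 fell from 140 ± 32.2 to 8.38 ± 2.31 CPM (−4.08 ± 0.43, adjusted p = 0.0003). Tgm3 fell from 58.6 ± 22.7 to 4.69 ± 4.84 CPM (−4.55 ± 0.21, adjusted p = 1.4e-05). Lower as well were the homeobox genes Alx1 (−4.13 ± 0.33) and Barx2 (−2.76 ± 0.41), Shisa3 (−4.01 ± 0.26), Nefm (−3.69 ± 0.39), Nup62cl (−3.63 ± 0.39), Pnliprp1 (−3.46 ± 0.46), the matrix gene Ecm1 (−3.24 ± 0.22) and the transcription factor Gata2 (−3.02 ± 0.43; adjusted p = 1.5e-05 to 0.0014).

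Of 28 Hox genes 17 fell (4 higher and 21 lower adjusted over the list alone), with Hoxa4 at −2.79 and Hoxa7 at −2.03 (adjusted p = 5.4e-09, and adjusted p = 0.52 with an estimated correlation). Of 23 cholesterol genes 11 fell (12 adjusted over the list alone), with Idi1 at −1.04 and Insig1 at −1.01 (0.00011, and adjusted p = 0.55 with an estimated correlation). Testis supporting genes rose in 12 and fell in 1 of 26 (15 and 2 adjusted over the list alone), with Ptgds at 3.20 and Tesc at 2.99 (4.1e-06, and adjusted p = 0.52 with an estimated correlation). Ovary supporting genes rose in 6 and fell in 5 of 26 (8 and 6 adjusted over the list alone; adjusted p = 0.24), with Adamts19 at 2.83, Gng13 at 2.66 and Foxl2 at 2.50. Dissociation stress genes fell in 8 of 23 (2 higher and 11 lower adjusted over the list alone), with the heat shock gene Hspa1a at −2.58 (0.00077, and adjusted p = 0.55 with an estimated correlation), where the E11.5 cells were sorted and the E12.5 gonad cells were not. Germ cell markers rose in 4 of 13 (4 adjusted over the list alone), with Mael at 3.32 and Dazl at 3.10 (0.00026, and adjusted p = 0.52 with an estimated correlation). The count of 3183 was 1795 without XX ridge E11.5 replicate 2, and 1776 without XY ridge E11.5 replicate 2. It was 5515 in the named clusters, where Tgm3 turned to 1.17 and Nup62cl (−1.23), Pnliprp1 (−0.47) and Pnliprp2 (−0.61) did not pass.

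Against the testis, Nr5a1-positive cells of the adrenal gland carried the enzymes of corticosteroid synthesis. Cyp21a1, the steroid 21-hydroxylase (chromosome 17, 34801348 to 34804561), was at least 1205-fold higher (97.1 ± 28.5 CPM against 0, adjusted p = 3.9e-05, n = 2 per group). Cyp11b1, the 11-beta-hydroxylase, was at least 942-fold (75.9 ± 3.47 CPM against 0, adjusted p = 1.9e-05). Ly6d was at 278 ± 56.0 against 0.358 ± 0.210 CPM (9.46 ± 0.38). The T-box gene Tbx20 was higher by 9.04 ± 1.37, the growth cone gene Gap43 by 8.93 ± 0.96 and Klhdc8a by 8.18 ± 0.65. Genes of sympathoadrenal cells were higher too: Phox2a by 8.70 ± 1.21, Dbh, the noradrenaline-making enzyme, by 7.91 ± 1.64 and the granin Chgb by 7.78 ± 1.08 (adjusted p = 4.3e-06 to 0.0033). Lower in the adrenal gland were Tmem184a (at least 614-fold, 144 ± 13.2 CPM in testis), Cbln4 (at least 209-fold), Hsd17b3, the testosterone-making enzyme (at least 202-fold, 47.3 ± 5.12 CPM) and Hoxd10 (at least 147-fold). Ctrb1 (at least 92.9-fold) and Shbg, the sex hormone-binding globulin (at least 87.4-fold), were lower with the cystatin Cst9 (−10.47 ± 1.46) and Amh (−8.40 ± 1.26; adjusted p = 1.6e-06 to 0.0014).

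**Figure D3:**
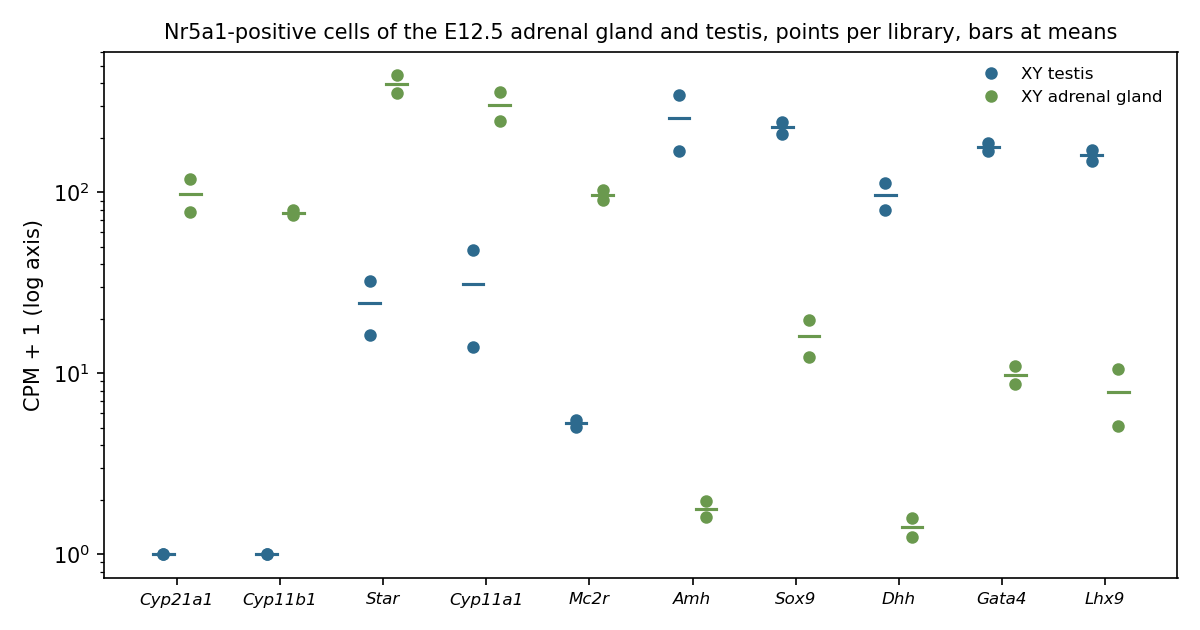
CPM of selected genes in Nr5a1-positive cells of the E12.5 adrenal gland and testis, with points per library and bars at the means (n = 2 each). Cyp21a1 has a mean of 97.1 CPM in the adrenal gland and 0 in the testis, and Amh 0.782 and 255 CPM.

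Of 23 steroidogenesis genes 16 rose and 5 fell (16 and 5 adjusted over the list alone), with the corticotropin receptor Mc2r at 4.48, its partner Mrap at 5.50, the cholesterol carrier Star at 4.08 and Cyp11a1 at 3.32 (adjusted p = 4e-11, and adjusted p = 0.081 with an estimated correlation). Of 26 testis supporting genes 22 fell (22 adjusted over the list alone), with Dhh at −7.96 and Sox9 at −3.94 (1.2e-18, and adjusted p = 0.081 with an estimated correlation). Of 30 coelomic epithelium and gonad specification genes 14 fell and 4 rose (14 and 5 adjusted over the list alone), with Emx2 at −7.82 and the gonadal transcription factors Wt1 (−4.66), Lhx9 (−4.57) and Gata4 (−4.35) (0.0011, and adjusted p = 0.081 with an estimated correlation). Hox genes split, 13 higher and 9 lower of 28 (15 and 10 adjusted over the list alone), with Hoxb8 at 6.29 and Hoxb6 at 5.66 and with Hoxd11 at least 10.6-fold lower (0.0071, and adjusted p = 0.69 with an estimated correlation). Ovary supporting genes fell in 16 and rose in 5 of 26 (16 and 6 adjusted over the list alone), with Wnt4 at 3.70 (0.021, and adjusted p = 0.31 with an estimated correlation). Shh rose (4.77) where Dhh fell, and the Notch target Hes5 was at −8.29 (6 of 15 Notch components fell, 7 adjusted over the list alone; 0.0022, and adjusted p = 0.31 with an estimated correlation). Imprinted genes rose in 11 and fell in 4 of 22 (14 and 4 adjusted over the list alone), with Cdkn1c at 3.01 and Dlk1 at 2.04 (0.0031, and adjusted p = 0.26 with an estimated correlation). Neural crest and chromaffin markers rose in 9 and fell in 3 of 12 (9 and 3 adjusted over the list alone), with tyrosine hydroxylase Th at 6.46 (0.0044, and adjusted p = 0.67 with an estimated correlation). Among those that fell were the glial genes Sox10 and Erbb3. Crest and chromaffin cells made up 39.5% of the gland. In all 5166 genes passed, 2151 higher and 3015 lower, and the adrenal positive cells were 74.1% adrenocortical. A further 12.6% lay in an unnamed cluster with markers of both cortical and chromaffin cells, 27.9% doublet calls and 2.71 times the median depth. Adrenal cells were sorted and testis cells were not, and only adrenal replicate 1 and testis replicate 2 share a date.

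Within the Wt1-positive cells of the ridge, cells with an Nr5a1 UMI differed from cells without one. At E10.5 Lhx9 was at 193 ± 51.3 CPM in positive and 27.2 ± 11.6 CPM in negative cells (2.86 ± 0.07, adjusted p = 1.9e-08, n = 4 libraries, all in this direction). Amhr2, the receptor of anti-Müllerian hormone, was at 104 ± 52.3 against 10.99 ± 7.46 (3.30 ± 0.08) and Nr6a1, an orphan receptor, at 269 ± 29.4 against 35.1 ± 7.37 (2.94 ± 0.10). Aldh1a1, an enzyme of retinoic acid synthesis (4.06 ± 0.13), the lipase Pnlip (3.99 ± 0.14), Kctd14 (3.76 ± 0.30), Cbln1 (3.65 ± 0.13), Sh2d4a (3.45 ± 0.10), Akr1cl (3.32 ± 0.08) and Chchd10 (3.04 ± 0.11) were higher. Lower were Prrx1 (−1.56 ± 0.10), Lhfp (−1.55 ± 0.14), Adamts18 (−1.55 ± 0.09), Crabp1 (−1.51 ± 0.10), the collagen receptor Ddr2 (−1.48 ± 0.13), Col9a1 (−1.44 ± 0.09), Foxd1 (−1.39 ± 0.09), Ebf1 (−1.36 ± 0.08) and Fli1 (−1.33 ± 0.09; adjusted p = 9.8e-09 to 3.9e-05). At E11.5 Kctd14 (3.49 ± 0.23), Dct (3.48 ± 0.23), the gonadal transcription factor Dmrt1 (3.39 ± 0.18), Mro (3.39 ± 0.31), Hsbp1l1 (3.24 ± 0.16), Barx2 (3.23 ± 0.19), Pglyrp1 (3.19 ± 0.24), Cst9 (3.15 ± 0.22) and Gpr37 (3.14 ± 0.19) were highest in positive cells. Gata2 (−2.48 ± 0.10), Agtr2, an angiotensin receptor (−2.35 ± 0.17), Lhfp (−2.33 ± 0.11), the neurotrophin receptor Ntrk2 (−2.33 ± 0.14), the proteoglycan Lum (−2.31 ± 0.23), Alx1 (−2.20 ± 0.11) and Prrx1 (−2.16 ± 0.09) were lower (adjusted p = 2.4e-06 to 9.8e-05).

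Of 16 steroidogenesis genes at E10.5, 12 rose and 1 fell (12 and 2 adjusted over the list alone), with Nr0b1 at 3.44, Cyp11a1 at 3.34 and Star at 2.92 (adjusted p = 4.1e-15, and adjusted p = 0.16 with an estimated correlation). Of 19 at E11.5, 14 rose and 3 fell (14 and 3 adjusted over the list alone; 1.7e-07, and adjusted p = 0.13 with an estimated correlation). Testis supporting genes rose in 9 and fell in 2 of 18 at E10.5 (9 and 2 adjusted over the list alone), with Dmrt1 at 4.59 and Inhbb at 4.05 (2.5e-08, and adjusted p = 0.36 with an estimated correlation). They rose in 20 of 23 at E11.5 (20 adjusted over the list alone; 1.3e-06, and adjusted p = 0.67 with an estimated correlation). Hox genes fell in 21 and rose in 2 of 28 at E10.5 (21 and 2 adjusted over the list alone; 7.3e-10, and adjusted p = 0.40 with an estimated correlation). At E11.5 they fell in 25 and rose in 2 of 29, with Hoxb2 at −2.13 (25 and 2 adjusted over the list alone; 1.1e-23, and adjusted p = 0.13 with an estimated correlation). Mesenchyme and matrix genes fell in 18 and rose in 5 of 27 at E10.5 (19 and 6 adjusted over the list alone; 8.6e-07, and adjusted p = 0.45 with an estimated correlation). By E11.5 it was 22 and 3 of 27, with Col1a1 at −1.81 (22 and 3 adjusted over the list alone; 2.9e-21, and adjusted p = 0.15 with an estimated correlation). Hypoxia and glycolysis genes rose in 16 of 19 at E10.5 (16 adjusted over the list alone; 5.8e-08, and adjusted p = 0.44 with an estimated correlation). At E11.5 it was 18 of 19, with the glycolytic enzymes Aldoa (1.47) and Eno1 (1.29) (18 adjusted over the list alone; 9.8e-14, and adjusted p = 0.11 with an estimated correlation). Nephric markers fell in 9 of 10 at E10.5, with Lhx1 at −1.41 (9 adjusted over the list alone; 3.9e-05, and adjusted p = 0.43 with an estimated correlation). In all 4603 genes passed at E10.5, 2416 up and 2187 down, and 9009 at E11.5, 4555 up and 4454 down. The E10.5 count was 2923 without XX ridge replicate 2, 3042 without XY ridge replicate 2 and 1118 without the library block. Positive cells were deeper at E11.5, with median depths of 20553 to 22362 UMIs against 14586 to 17210.5. With negative cells matched on depth the count was 5338, but matching left 36 to 272 negative cells per library in place of 1214 to 2553.

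In germ cells at E12.5 the sexes had entered different programs. Ovary germ cells lay mostly in 1 cluster (93.4% and 93.2% by replicate) and testis germ cells in another (93.2% and 90.1%), and a cluster with 98.4% doublet calls held 3.54 to 8.09% per library. The Nodal antagonist Lefty1 was at 197 ± 25.4 CPM in testis and 4.41 ± 3.33 in ovary (5.46 ± 0.56, adjusted p = 0.0083, n = 2 per group). Its relative Lefty2 (5.36 ± 0.94) was higher with Otx2 (4.40 ± 0.59), the cell death gene Pmaip1 (4.48 ± 0.48) and Hesx1 (3.49 ± 0.34; adjusted p = 0.0074 to 0.025). Stra8 was at 5.06 ± 0.649 CPM in testis and 182 ± 79.6 in ovary (−5.19 ± 0.38, adjusted p = 0.0046). Lower with it were the imprinted Phlda2 (−6.04 ± 0.23), its neighbour Slc22a18 (−4.99 ± 0.24), the homeobox gene Cdx2 (−4.95 ± 0.26), Gata2 (−4.57 ± 0.23), Rec8 (−4.20 ± 0.39), Porcn, which prepares WNT ligands for secretion (−3.70 ± 0.19), and Calcoco2 (−3.38 ± 0.33; adjusted p = 0.0015 to 0.0074). Of 17 female germ cell and meiosis genes 12 fell and 5 did not pass (13 adjusted over the list alone; adjusted p = 1.2e-13, and adjusted p = 0.38 with an estimated correlation). Of 17 male germ cell genes 7 rose (8 adjusted over the list alone), with the Nodal co-receptor Tdgf1 at 4.73 and Nodal at 3.12 (2.1e-06, and adjusted p = 0.33 with an estimated correlation). Genes of supporting cells moved as well: Ptgds (4.11 ± 0.69) and Defb19 (4.21 ± 0.55) were higher. Testis supporting genes rose in 14 and fell in 1 of 24 (17 and 1 adjusted over the list alone), with Dhh at 4.30 (6.5e-14, and adjusted p = 0.33 with an estimated correlation). Ovary supporting genes fell in 9 and rose in 1 of 25 (12 and 1 adjusted over the list alone), with Irx3 at −4.37 (4.6e-06, and adjusted p = 0.40 with an estimated correlation). Ptgds (5.16 ± 0.67) and Defb19 (5.53 ± 0.59) were higher in testis endothelium too, so their shift was not particular to germ cells. Free RNA was not tested as their source. In germ cells, of 1416 genes 654 were higher and 762 lower in testis. The count was 356 without testis replicate 1 and 433 without testis replicate 2, and 5325 with dates as blocks.

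Outside the germ line, coelomic epithelium and gonadal progenitors of the testis had less Irx3 (−8.41 ± 0.60, 0.291 ± 0.058 against 97.6 ± 51.7 CPM, adjusted p = 0.0072, n = 2 per group), Fst (−4.19 ± 0.29), Lgr5 (−4.03 ± 0.34), the KIT ligand Kitl (−3.89 ± 0.29, 10.4 ± 1.49 against 153 ± 48.3 CPM) and Kctd14 (−3.41 ± 0.24). They had more Cbln1 (4.78 ± 0.51), the microfibril gene Mfap4 (2.50 ± 0.23), the myosin light chain kinase Mylk (1.91 ± 0.21) and the FGF antagonist Spry1 (1.84 ± 0.18; adjusted p = 0.0072 to 0.025). The class joined clusters unequally: 1 held 54.4% and 51.1% of its cells in the ovary replicates, and another 43.7% and 47.7%, against 97.8% in each testis. Of 25 ovary supporting genes 14 fell (20 adjusted over the list alone), with Irx5 at −5.34 and Msx1 at −3.41 (adjusted p = 6.1e-60, and adjusted p = 0.25 with an estimated correlation). This class had 148 genes, 622 without testis replicate 1, 405 without testis replicate 2, 377 in the DESeq2 Wald test, 458 with no filter on low counts and 1119 with dates as blocks. In mesonephric and other mesenchyme 17 genes passed. The peptidase Enpep (3.27 ± 0.21, 77.0 ± 1.85 against 7.95 ± 1.69 CPM, adjusted p = 0.0085) was higher in testis whichever library was left out, although these fits have 1 library in an arm and 1 residual degree of freedom. The count was 5 without ovary replicate 1, 7 without ovary replicate 2, 68 and 122 without testis replicates 1 and 2, 99 in DESeq2, 147 with no filter and 74 with blocks. In endothelium 14 genes passed, a count that moved with the libraries (31, 4, 133 and 168 without ovary replicates 1 and 2 and testis replicates 1 and 2). In erythroid cells 2 passed, with Xist at −6.31 ± 0.49 (59 without ovary replicate 2, 39 without testis replicate 1), and 181 had an unadjusted p under 0.05. In interstitial progenitors, with 26 and 250 cells in ovaries and 30 and 2408 in testes, 24 passed, among them Cyp17a1 (at least 7.74-fold higher) and Osr2 (4.12 ± 0.40). None but Xist passed without testis replicate 1 (count 1, with 342, 95 and 124 without ovary replicates 1 and 2 and testis replicate 2).

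Whole libraries gave a view at every stage, E9.0 included, but their values also move with the makeup of cells. Neural tube and neuron cells were 4.30 ± 2.81% of XX and 12.4 ± 5.54% of XY trunks (SD, n = 2). At E9.0, Eif2s3y was at least 1243-fold and Ddx3y at least 783-fold higher in XY, and Xist fell by 9.20 ± 1.15 (adjusted p = 0.0028 to 0.011, n = 2 per group). Of 388 genes 300 were higher and 88 lower, with the supporting cell lists at 0 of 27 in the testis list and 1 higher of 26 in the ovary list. Only 2 of the higher and 2 of the lower genes had at least 20 CPM and no overlap between libraries. X inactivation and escape (2 lower of 11, 5 adjusted over the list alone) held with an estimated correlation (adjusted p = 0.012). The count was 109 and 96 without XX trunk replicates 1 and 2, 221 and 204 without XY trunk replicates 1 and 2, and 5 in a fit of the 4 libraries. Eif2s3y and Ddx3y did not pass without XX trunk replicate 1 (adjusted p = 0.0846 and 0.0976), without XX trunk replicate 2 (0.0964 and 0.111) and with blocks (0.0762 and 0.0815). At E10.5, only 3 higher and 3 lower genes of the 355 that passed had at least 20 CPM and no overlap. Ddx3y (at least 1832-fold), Eif2s3y (at least 1604-fold) and Xist (−11.09 ± 1.25) led these 355 genes. The count was 8, 6 and 2 without XX ridge replicate 1, XX replicate 2 and XY replicate 1, 0 with blocks in edgeR and 5 in a fit of the 4 libraries. Ddx3y and Eif2s3y did not pass without XX ridge replicate 1 (0.0972 and 0.0996), XX replicate 2 (0.159 for both) or XY replicate 1 (0.0633 for both), and Xist not without XY replicate 1 (0.0633).

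At E11.5, whole XY ridges had more Sox9 (124 ± 15.7 against 55.5 ± 2.88 CPM, 1.16 ± 0.14, adjusted p = 0.0025, n = 2 per group) and the sialyltransferase St3gal4 (1.17 ± 0.14), and less Fst (−1.41 ± 0.26; adjusted p = 0.0022 to 0.019). Testis supporting genes rose in 10 of 27 (17 adjusted over the list alone), and the list held with an estimated correlation (adjusted p = 0.0042). Among all genes that passed, 13 higher and 5 lower had at least 20 CPM and no overlap between libraries. Of 406 genes, 4 passed without XX ridge replicate 1 (Sox9 1.11, St3gal4 1.13 and Fst −1.03, none passing), 27 without XX replicate 2, and 57 without XY replicate 1 and 31 without XY replicate 2 (Fst −1.15, not passing). It was 153 in DESeq2, 17 with blocks and 4 in a fit of the 4 libraries, where Sox9 (1.15), St3gal4 (1.16) and Fst (−1.42) did not pass. At E12.5, 3455 genes passed, 1769 higher and 1686 lower in testis (2057 without ovary replicate 1, 2090 without testis replicate 1 and 2046 in a fit of the 4 libraries). Amh was at 5.87 ± 1.02, Prokr2, a prokineticin receptor, at 4.74 ± 0.34, Irx3 at −6.80 ± 0.41, Fst at −6.17 ± 0.33, Stra8 at −5.85 ± 0.32 and Adam8 at −3.48 ± 0.32 (adjusted p = 4.6e-07 to 0.0015). Testis supporting genes rose in 21 of 27 (24 adjusted over the list alone). Ovary supporting genes fell in 18 of 26 (19 adjusted over the list alone). Both held with an estimated correlation (adjusted p = 0.017 for each).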

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

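Apart from the planned test of the change of the sex difference from E11.5 to E12.5, the tests in this part were chosen only after the results they examine had been seen.

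In germ cells at E12.5, X-linked genes were lower in testis as a group, a pattern not examined above. Among 195 X-linked genes with at least 20 CPM, 171 (87.7%) were lower in XY, with a median log2 fold change of −0.63, against 0.07 for 5720 autosomal genes. A shift of all genes from the scaling would move the autosomes too, and the lowest median of the 19 autosomes was 0.00614. Without the multicopy families of the X chromosome the median was −0.64 over 180 genes. With 171 of 195 genes lower, leaving out so few could hardly move a median, so this was no test of the families. The 171 genes show a shift over most X-linked genes. The hypothesis of 2 active X chromosomes in XX germ cells at this stage may account for it: Xist in ovary germ cells was at 76.9 ± 36.8 CPM against 1210 to 2424 in other classes with erythroid cells left out (4.21% and 7.40% of the lowest), while erythroid cells of ovaries had as little, 81.6 ± 22.5 CPM.

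XX ridge E11.5 replicate 2, ovary replicate 1 and XY ridge E11.5 replicate 2 held cells with transcripts of the other sex: 47, 67 and 100. Free RNA from another library would spread evenly over the cells, and the smallest ratio of observed cells to an even spread was 2.45. Droplets with a cell of each sex would carry transcripts of both, and of all cells with at least 2 UMIs of the other sex (70, 103 and 165) at most 32.1% also had 2 of their own. Barcodes shared with a library of the other sex and the same date made up 0% of the 47, 67 and 100 cells. Whole cells of the other sex may be present in ovary replicate 1: in clusters made without Y-linked genes and Xist, 46.3% of the 67 (Clopper-Pearson interval 34.0 to 58.9) were Sertoli cells or in the germ cluster of the testis, against 30.9% of testis cells and 0.454% of the other cells of that library, and this was not tested in the ridges.

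At E9.0, GFP was found in nephric cells that had few Nr5a1 transcripts: 42.0 ± 7.50% of these cells had a GFP UMI (SD, n = 4 libraries), at 119 ± 50.2 CPM, and an Nr5a1 UMI was in 0.499 to 1.97%. Other cells had a GFP UMI in 3.43 to 5.08%. Free RNA would not favour these cells, and their GFP level was at least 28.4 times the highest of any other cluster. Doublets with cells that express both would bring Nr5a1 along, and Nr5a1 UMIs per GFP UMI reached at most 12.7% of those of E10.5 coelomic cells. A larger depth would raise the share, and the median UMI count was at most 1.00 times that of the other cells. Activity of the transgene with little Nr5a1 in these cells was not tested.

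The sex difference in Nr5a1-positive cells changed from E11.5 to E12.5 for 590 genes. In the comparison of Nr5a1-positive with negative cells at E10.5, XX ridge replicate 1 stood apart for Akr1cl (2.52, others 3.07 to 3.16). XY ridge replicate 1 stood apart for Lhfp (−2.20, others −1.34 to −1.19) and for Foxd1 (−1.66, others −1.25 to −1.18). Of 40 genes tested this way 3 were found, where about 1 in 20 is expected by chance.

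The 8 libraries of each stage comparison come from 4 dates, and only 3 splits of 4 against 4 keep the libraries of a date together, too few to exclude chance. For E11.5 against E10.5 the real split, fitted without sex, gave 6626 genes and the highest other of these 0, and for E12.5 against E11.5 1751 and 0, with 1 as large in each. Among all 35 splits the highest other had 2 and 360 genes, the latter for the split of XX from XY libraries. In the comparisons of positive with negative cells, 8 splits are too few as well, with 4603 and 9009 genes for the real labels, 0 for the highest other and 1 as large in each.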

How the results depend on the processing

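Leaving out the cells with transcripts of the other sex was the one alternative chosen only after the data had been seen. Of 428 gene results named by the rule or as list members, 324 kept their call in every alternative, 101 lost it in at least 1 and 5 turned direction; a result can be among both. Of 5453 alternative values of genes 5122 were the same. Why a value moved was not tested unless a cause is given.

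All 5 that turned did so in all cells of the clusters with a steroidogenic, supporting or coelomic name, which at E11.5 are almost all coelomic and at E12.5 leave out the unnamed cluster led by Cyp17a1: Frmd6 in the sex comparison at E11.5 (0.029), Tgm3 from E11.5 to E12.5 (1.17), Cyp17a1 in the change of the sex difference (−1.36), and Cyp17a1 (−0.86) and Cyp11a1 (−0.55) in the sex comparison at E12.5. In those clusters the number of genes was 1 for the sex comparison at E11.5, 3354 from E10.5 to E11.5, 5515 from E11.5 to E12.5 and 1139 for the change.

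Leaving out 1 library at a time gave 0 to 6 genes for sex in Nr5a1-positive cells at E10.5, 3 to 21 at E11.5 and 1842 to 1966 at E12.5. The range was 1776 to 2424 from E11.5 to E12.5 and 137 to 370 for the change of the sex difference. In whole libraries it was 96 to 221 at E9.0, 2 to 271 at E10.5, 4 to 57 at E11.5 and 2057 to 2903 at E12.5. Among classes it was 134 to 622 in coelomic cells, 4 to 168 in endothelium, 2 to 59 in erythroid cells, 356 to 1798 in germ cells, 1 to 342 in interstitial progenitors and 5 to 122 in mesonephric mesenchyme. Positive against negative cells at E10.5 gave 2923 to 4699. The counts for adrenal against testis, E11.5 against E10.5 and positive against negative cells at E11.5 stayed within 1.5 times.

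With dates as blocks the number of genes was 0 at E10.5, 4991 at E12.5 and 1358 for the change. In whole libraries it was 0 at E10.5 and 17 at E11.5, where 7 lists were called in place of 4. In classes it was 1119 coelomic, 67 endothelial, 6 erythroid, 5325 germ, 107 interstitial and 74 mesonephric. Blocking changed no other count of genes by more than 1.5 times.

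A fit of the compared groups alone gave 5 genes at E10.5 and 35 at E11.5 in positive cells, and 5, 5, 4 and 2046 in whole libraries at E9.0, E10.5, E11.5 and E12.5. Without the library block, positive against negative cells at E10.5 gave 1118 genes. With negative cells matched on UMIs per cell, E11.5 gave 5338, from far fewer negative cells.

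The DESeq2 Wald test called 9 genes at E10.5 and 149 at E11.5 in positive cells, 153 in whole libraries at E11.5, and 377 coelomic, 27 endothelial, 4 erythroid, 45 interstitial and 99 mesonephric genes. With no filter on low counts the classes had 458 coelomic, 165 endothelial, 47 erythroid, 266 interstitial and 147 mesonephric genes. At least 2 Nr5a1 UMIs gave 174 genes at E11.5, and no cluster left out gave 344 for the change.

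Without cells that carry transcripts of the other sex, the sex comparison had 6 genes at E10.5 and 90 in interstitial progenitors. No E10.5 library held such cells, so the E10.5 count moved through the other libraries of the shared fit. Without doublets the endothelial count was 8 and the Sertoli share of testis cells 16.7%.

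Camera with an estimated correlation called 2 lists for sex in positive cells at E10.5 (18 with the preset), 3 at E11.5 (6) and 2 at E12.5 (14). It called 0 for adrenal against testis (14), 1 from E10.5 to E11.5 (13), 0 from E11.5 to E12.5 (12) and 1 for the change (12). In whole libraries it called 1 at E9.0 (5), 2 at E10.5 (13) and 3 at E12.5 (13). It called 0 in each class, where the preset called 15 coelomic, 12 endothelial, 8 erythroid, 12 germ, 12 interstitial and 15 mesonephric. For positive against negative cells it called 0 at E10.5 (12) and 0 at E11.5 (13).

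Class shares depended on the clustering: at resolution 0.5, 28 moved and 34 were the same, and at 2.0 it was 20 and 42. At 0.5 the interstitial progenitor share of testes was 46.0%, and unnamed cells were 16.97% and 14.6% in XX and XY at E11.5. The crest share of XX and XY trunks at E9.0 fell to 0. The shares given in the report for Sertoli cells in testes, pre-granulosa and germ cells in ovaries, adrenocortical and crest cells in adrenal glands and somite in trunks stayed within their spread at both resolutions.

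The share of cells with an Nr5a1 UMI rose with depth. Not thinned it was 0.393% and 0.314% in XX and XY at E9.0, 18.9% and 26.4% at E10.5, 29.6% and 37.1% at E11.5, 43.3% in ovaries and 54.3% in testes. Thinned to double the depth it was 0.167% in XX at E9.0, 14.5% and 22.0% at E10.5, 33.0% and 42.2% at E11.5, and 32.9%, 51.4% and 43.2% in ovaries, testes and adrenal glands. With at least 2 UMIs, not thinned, it was 0.0171% in XX at E9.0 and 19.8% in ovaries.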

Other observations

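GFP and Nr5a1 differed unequally between the testes in some classes. In Sertoli cells GFP was at 8722 CPM in testis replicate 1 and 2074 in replicate 2, a ratio of 4.21, where Nr5a1 had a ratio of 1.29. The ratio for GFP was 4.30 in coelomic cells, 6.52 in interstitial progenitors and 3.64 in endothelium, where Nr5a1 had 1.90, 2.78 and 1.74; the interstitial ratio rests on 30 cells in replicate 1 against 2408 in replicate 2. In germ cells (2.36 and 2.47) and mesonephric mesenchyme (2.05 and 1.92) the ratios for GFP and Nr5a1 were alike. The transgene dose of the embryos is not known. The testes also differed in the cluster led by Cyp17a1, Ren1 and Cbln1, with 1360 cells in replicate 1 and 156 in replicate 2, where GFP was at 4702 and 4134 CPM. Ovaries held 230 and 8 such cells.

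The G2 and M phase genes, of which 0 of 26 differed between the sexes at E11.5, were all higher in testis at E12.5 (adjusted p = 0.16 for the list with an estimated correlation, and 0.18 for the change). The compared cells differed in kind, 72.1% pre-granulosa in ovaries and 35.8% Sertoli in testes.

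X inactivation may differ between germ cells and their neighbours before E12.5 as well, a hypothesis from these data. Xist in XX germ cells was at 73.8 and 67.5 CPM in the ridges at E11.5. In ovary germ cells it was at most 7.40% of the lowest other class, erythroid cells left out. At E9.0 the gap was smaller: 22 germ cells of XX trunk replicate 1 had 227 CPM, against 803 to 1290 CPM in its other named classes, erythroid cells and classes under 20 cells left out. An allele-resolved count of X-linked transcripts in single germ cells from E10.5 to E13.5 would test the hypothesis. Outside the genes that escape X inactivation, transcripts of both X chromosomes in the same cell are expected only if both are active.

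The Wt1-positive cells without an Nr5a1 UMI at E11.5 had a GFP UMI in 68.8 to 79.4% of cells, against 94.2 to 98.0% of the positive cells. The share that free RNA alone gives was not measured. As a level, GFP was at 303 to 562 CPM in the negative cells and 2381 to 3705 CPM in the positive cells. A germ cluster mostly from E11.5 had a level of 0.657 GFP UMIs per 10000. Sorting on GFP before sequencing would part the groups by protein in place of a single UMI.

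The E9.0 nephric cells with GFP may mark activity of the transgene where few Nr5a1 transcripts are made. Nr5a1 per GFP reached at most 12.7% of that of E10.5 coelomic cells. Nr5a1 was not absent, with 17 UMIs beside 4540 of GFP. The nephric cluster held 40% of the Nr5a1-positive cells of XX trunks and 38.1% of those of XY trunks. In situ hybridisation for both transcripts on E9.0 trunks would show whether the same cells carry them.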
